A study of Microbacterium resistens with 6 samples.

How the data were processed

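RNA was sequenced from *Microbacterium resistens* strain MZT7, a bacterium, in 3 control samples and 3 samples treated with 17β-estradiol (E2, a steroid oestrogen) at 20 mg/L. Per the labels' protocols, 3 μg of total RNA entered each library, and libraries were made with a NEBNext Ultra RNA kit, for which no strand marking is stated. The labels give each sample its group and number. They do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

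The deposited table lists 3890 features on 1 chromosome, with 3785 coding genes, 79 predicted transcripts outside the coding set and 26 small RNAs. It holds the authors' raw counts per feature, which the submitters' processing notes tie to HTSeq 0.6.1. It also holds the authors' FPKM values, whose divisor was proportional to a median-of-ratios size factor in each library when checked against the counts. The deposited signal columns are the authors' mean normalised counts per group. The authors' deposited log2 fold changes, p-values and adjusted p-values compare E2 with control, and the notes name DESeq 1.18.0. Aligner, genome build and counting strand are not given in the sources used here, so coordinates are those of the deposited table, counted from 1. Of the small RNAs 16, and of the predicted transcripts 72, lie at least 50% opposite a coding gene. Without stated strand-specific counting, reads of such pairs cannot be told apart, and their values are uncertain.

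The deposited table carries no gene symbols. Domain names (Pfam short names) stand in a column for 1507 of the 3785 coding genes, and genes are named here by their identifiers and domain names. A domain name gives a protein family, not a measured function.

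The test fixed at the outset was limma-trend on log2(FPKM + 1), with edgeR to be used if counts were present. Because counts were present, edgeR 4.0.16 quasi-likelihood tests (TMM normalisation, no replicate block) in R 4.3.3 are the main test, and limma-trend became an alternative. Features with a mean FPKM of at least 1 were tested, 3868 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were obtained as the absolute log2 change divided by the square root of the F statistic.

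A total of 26 gene lists were also fixed beforehand, as patterns for product descriptions. Those patterns could not be matched without descriptions, so each list was mapped to domain names after the annotation was seen and before any list was tested. With a minimum of 5 tested members, 17 lists were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry. The other 9 had too few members, and 2 of these had none. They were ribosomal proteins, oxidative phosphorylation, glycolysis, the phosphotransferase system, iron-sulfur cluster assembly, cold shock proteins, cell division, flagella and terpenoid synthesis. Runs of at least 4 neighbouring called genes were compared with 1000 shuffles of the calls.

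Genes were named by a rule fixed beforehand. It takes the largest rises and falls among called genes with a description, called members and the member with the highest mean FPKM of each list, called or steroid-described short-chain dehydrogenases, called genes with no description, and the 5 genes with the highest mean FPKM per group. With 1 called gene, the rule gave few names. The other genes named were chosen after their values were seen, mostly from the 27 calls of the authors' deposited table and their neighbours. Of the list members given by the rule, those of lists not described in the results are left out.

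A library's weak-gene level is its median count per kb over 323 weakly expressed features, the lowest 10% by mean FPKM with a length of at least 300 bp. Alternatives chosen before the data were examined were other pseudocounts, filters, scalings, a replicate block, limma without trend and leaving out each library. Alternatives added after seeing the data were DESeq2 1.42.0, the weak-gene level as a covariate, subtraction of an estimated even background followed by voom and limma, leaving out pairs of libraries, and testing coding genes only. The even background was estimated from a line fitted to each library's counts per kb against those of control 3. Its intercept was 640 and 285 counts per kb in E2 libraries 1 and 2, above their weak-gene levels of 354 and 156. Subtraction may thus take off more than an even background.

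The tests were tested on simulated counts with the spread of these libraries, over 3868 features. The edgeR test recovered 14% of genes changed 2-fold and 81% of genes changed 4-fold, with 5 unchanged genes called. DESeq2 recovered 23% and 91% with 22 unchanged genes called, and limma-trend 14% and 73% with 3. With an even background added at the estimated levels edgeR recovered 13% and 49%. There the RNA part of each library was scaled by its total and TMM factor, which was 1.53 in E2 library 1 and 0.71 in control 3. The line fitted to the data had a slope of 0.43 in E2 library 1. The simulated libraries thus lacked the balance of RNA and background fitted to the data. Total counts per library lay between 4105374 and 4858150.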

Results

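Transcript levels were measured by RNA-seq in *M. resistens* MZT7 with and without 20 mg/L E2, with 3 libraries per group, to learn how the strain degrades E2 and how it responds to it at the transcript level. Control libraries 1, 2 and 3 held 4298903, 4681321 and 4637004 counts, and E2 libraries 1, 2 and 3 held 4194718, 4858150 and 4105374. No 2 libraries were alike within sampling noise, with a lowest chi-square per degree of freedom of 44.2.

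Under E2, MZT7_GM000628, a gene with a pyridine nucleotide-disulphide oxidoreductase domain (Pyr_redox_2), rose from 23.4 ± 4.71 to 119 ± 7.55 FPKM (SD, n = 3 each). Its log2 change was 2.43 (SE 0.25, edgeR adjusted p = 0.0306), and all 3 E2 libraries lay above all 3 controls. It lies on chromosome 1 at 672569 to 673720. It was the 1 feature of 3868 past the threshold, and 0 features fell by edgeR. At an unadjusted p under 0.05 there were 934 features, 710 higher and 224 lower with E2. Without E2 replicate 3 the edgeR calls were 831 higher and 292 lower. The call of MZT7_GM000628 was lost without control replicate 1 (edgeR adjusted p = 0.271), control replicate 2 (0.208), control replicate 3 (0.184) or E2 replicate 2 (0.343), with log2 changes from 2.34 to 2.55. It was also lost under limma-trend on log2(FPKM + 1), the test fixed at the outset (limma adjusted p = 0.0693, log2 change 2.31), which called 0 features in all and gave 706 at an unadjusted p under 0.05. Its limma adjusted p was 0.0689 with a pseudocount of 0.1 (log2 change 2.35), 0.146 without trend (2.31), 0.0795 with quantile normalisation (1.89) and 0.571 with voom after subtraction of a background (5.41, SE 1.51). DESeq2 called 3 features higher and 32 lower, and gave no adjusted p for 2774 features, MZT7_GM000628 among them.

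The authors' deposited table lists 27 features at an adjusted p under 0.05, 11 higher and 16 lower with E2, and MZT7_GM000628 has the smallest p-value there. All 27 had E2 and control libraries that did not overlap in FPKM. Over all tested features, 911 did not overlap, or 23.6%, where chance gives 10%. Of these, 421 were higher and 490 lower with E2.

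Libraries differed within the E2 group. The weak-gene level was 57.9, 49.2 and 18.3 counts per kb in controls 1, 2 and 3, and 354, 156 and 44.8 in E2 libraries 1, 2 and 3. Weakly expressed genes were higher and strongly expressed genes lower in E2 libraries 1 and 2, while E2 library 3 followed the controls. Among genes cut into 3 equal parts by level, in the weakest part the median log2 difference from the controls was 1.80, 1.00 and 0.10 in E2 libraries 1, 2 and 3, and in the strongest part it was -1.28, -0.55 and -0.10. The first principal component held 81.4% of the variance.

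**Figure D1:**
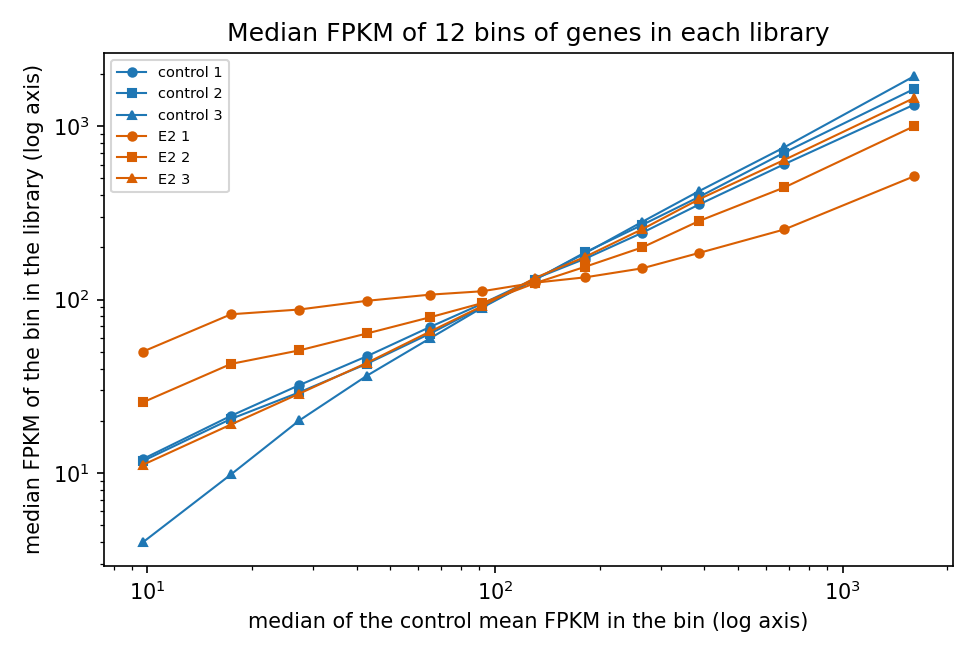
Median FPKM of 12 bins of genes in each library (y axis, log scale) against the median control mean FPKM of the bin (x axis, log scale); blue lines are controls, orange lines E2 libraries, and marker shapes give the replicate. In the highest bin E2 library 1 had a median of 513 FPKM and E2 library 2 of 997, against 1450 in E2 library 3 and 1328 to 1936 in the controls, and in the second lowest bin the order was turned, with 82.2, 42.5 and 19.0 FPKM in E2 libraries 1, 2 and 3 and 9.82 to 21.4 in the controls.

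MZT7_GM000628 lies in a stretch of 8 genes, MZT7_GM000626 to MZT7_GM000633 (671036 to 678168), chosen for description after its values were seen. MZT7_GM000626, of the major facilitator superfamily (MFS_1), a family of membrane transporters, was at 21.2 ± 7.24 FPKM in controls and 102 ± 8.42 with E2 (SD, n = 3; log2 change 2.35, SE 0.31, edgeR adjusted p = 0.0931). MZT7_GM000633, with a universal stress protein domain (Usp), was at 37.0 ± 13.5 and 139 ± 69.7 FPKM (log2 change 1.95, SE 0.48, edgeR adjusted p = 0.201). These 3 genes had every E2 library above every control. In MZT7_GM000629, MZT7_GM000630 (E1-E2_ATPase, a cation pump domain), MZT7_GM000631 and MZT7_GM000632, E2 library 1 lay below control 3, so the groups overlapped. The log2 changes of these 4 genes were 1.87, 2.30, 2.27 and 2.46, with SEs from 0.71 to 1.09. MZT7_GM000627 overlapped through E2 library 3, at 40.3 FPKM against 48.6 in control 2, with a log2 change of 1.74 (SE 0.88). The median log2 change over the 8 genes was 2.28. In E2 library 1, MZT7_GM000626 was at 103 FPKM, where the bins with median control means of 17.4 and 27.3 FPKM had medians of 82.2 and 87.6.

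A second transporter of the same family, MZT7_GM003584 (MFS_1, 3811832 to 3813487), was at 97.7 ± 19.6 FPKM in controls and 369 ± 73.2 with E2 (SD, n = 3; log2 change 1.98, SE 0.28, edgeR adjusted p = 0.0969). Its neighbour MZT7_GM003583, of the MarR family of transcription regulators, was at 99.4 ± 8.34 and 252 ± 100 FPKM (log2 change 1.40, SE 0.31, edgeR adjusted p = 0.201). MZT7_GM000095 (102306 to 103142), a short-chain dehydrogenase (adh_short), the family that holds many hydroxysteroid dehydrogenases, was at 159, 42.5 and 27.0 FPKM in controls and 198, 528 and 1035 with E2. Its log2 change was 2.98 (SE 0.77, edgeR adjusted p = 0.201), and 2.30 without E2 replicate 3. Beside it, MZT7_GM000096, of the TetR family of transcription regulators, was at 73.7 ± 5.13 and 167 ± 36.0 FPKM, and MZT7_GM000094, an ABC transporter membrane domain gene, at 29.2 ± 12.1 and 84.7 ± 20.0 FPKM. MZT7_GM000094 was at 107, 79.5 and 67.9 FPKM in E2 libraries 1, 2 and 3, falling in the order of their weak-gene levels. Its log2 change was 1.63, and 0.98 with the weak-gene level as a covariate, and it had no value after subtraction. None of these 5 genes passed the edgeR test. The authors' deposited table calls MZT7_GM003584, MZT7_GM000095 and MZT7_GM000096.

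**Figure D2:**
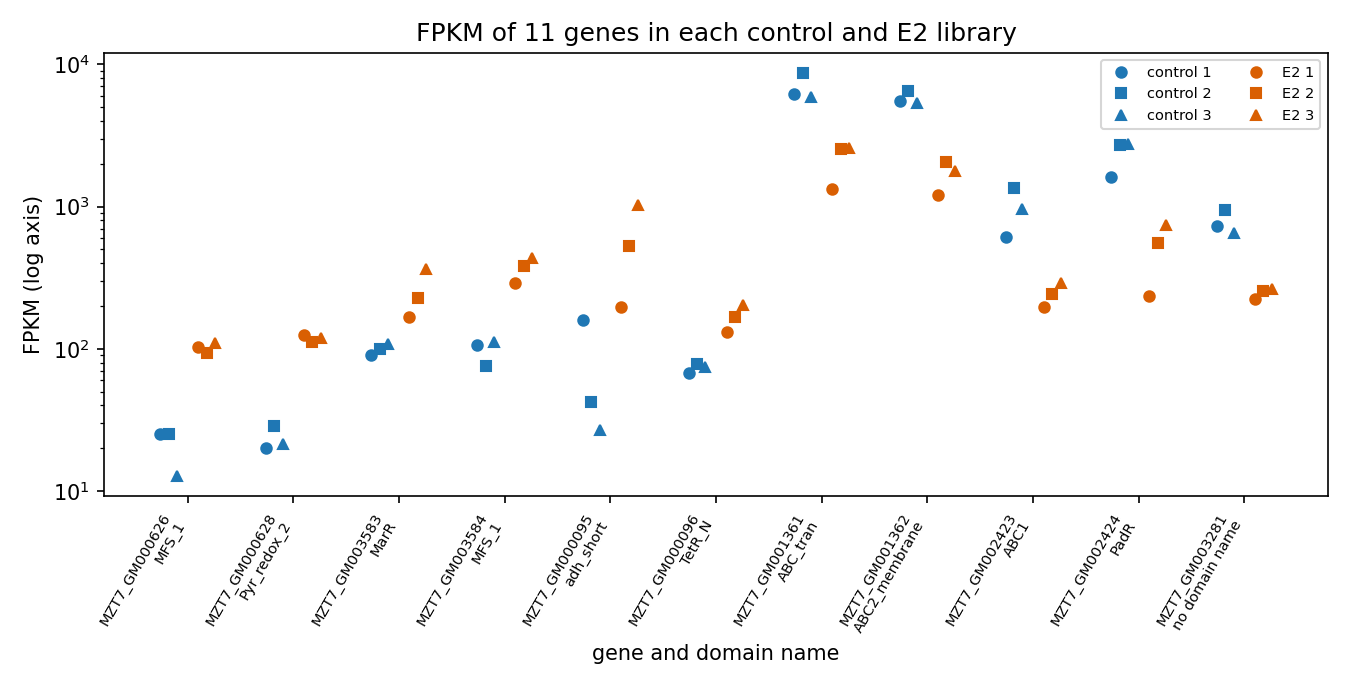
FPKM (y axis, log scale) of 11 genes (x axis, with domain names) in each library; blue points are controls, orange points E2 libraries, and marker shapes give the replicate. In each gene the 3 E2 points lie on one side of the 3 control points, and MZT7_GM000628 alone passed the edgeR test.

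Of the genes lower with E2, 0 passed the edgeR test. Several with the larger differences were neighbours. MZT7_GM001061, which overlaps Novel00028 on the other strand (log2 change -1.65), MZT7_GM000868 and MZT7_GM001267 had log2 changes of -1.88, -1.29 and -1.31. MZT7_GM001361 and MZT7_GM001362, the ATP-binding and membrane parts of an ABC transporter by their domains, were at 6935 ± 1532 and 5806 ± 649 FPKM in controls and at 2157 ± 714 and 1684 ± 441 with E2 (SD, n = 3). Their log2 changes were -1.61 (SE 0.51) and -1.71 (SE 0.43). MZT7_GM002424, of the PadR family of transcription regulators, had a log2 change of -2.16 (SE 0.45), and its neighbour MZT7_GM002423 (ABC1) one of -1.92 (SE 0.37). MZT7_GM002424 overlaps Novel00054 on the other strand, whose log2 change was -1.76. In MZT7_GM003280, MZT7_GM003281 and MZT7_GM003282 (ABC_tran) the log2 changes were -1.34, -1.56 and -1.03. The authors' deposited table calls 9 of these 10 coding genes, the exception being MZT7_GM003282. The genes were picked from its calls and their neighbours, so this number was set by the choice. Without E2 replicate 3, 8 of the 10 passed the edgeR test, with MZT7_GM001361 (edgeR adjusted p = 0.0540) and MZT7_GM003282 (0.0784) as the exceptions. In that setting 292 features were called lower, and 26 of the 27 deposited calls passed. After subtraction of a background, the log2 changes of the 10 genes ran from -0.61 in MZT7_GM000868 to -1.69 in MZT7_GM002424. Each was smaller than before subtraction, and 0 features passed as lower.

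All 12 genes from MZT7_GM003502 to MZT7_GM003513 (3729619 to 3734933) were lower in every E2 library than in every control, with a median log2 change of -0.88. Predicted transcripts on the opposite strand of this stretch carry domain names of ribosomal proteins, among them Novel00071 (Ribosomal protein S17) and Novel00074 (Ribosomal protein S8). Such a name may be that of the coding gene opposite, since Novel00054 has a PadR name and lies opposite MZT7_GM002424 (PadR). Which strand holds the ribosomal protein genes was not checked. MZT7_GM003509 had 1377 ± 141 FPKM in controls and 650 ± 161 with E2 (SD, n = 3), and MZT7_GM003513 had 2298 ± 101 and 1092 ± 365 FPKM. The translation elongation factor domain gene MZT7_GM003469 (GTP_EFTU) was at 1732 ± 271 and 753 ± 255 FPKM. The strongest of the 3 parts of all genes was also lower in E2 libraries 1 and 2. MZT7_GM003512 was weaker, at 31.5 ± 8.38 FPKM in controls (SD, n = 3, log2 change -1.25, SE 0.54). It is 186 bp long and overlaps Novel00075 on the other strand, so its value is uncertain. With the weak-gene level as a covariate the median log2 change of the stretch was -0.66, and 0 of its genes were called. After subtraction the changes ran from -0.085 in MZT7_GM003507 to -0.84 in MZT7_GM003510, with no value for MZT7_GM003512.

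Of the 17 gene lists tested, 3 were higher and 1 was lower with E2 by camera with its preset correlation, and 0 with an estimated correlation or by fry. Major facilitator transporters had 63 tested members, of which 54 had a positive log2 change, with a median of 1.00 (camera adjusted p = 1.02e-06, and adjusted p = 0.814 with an estimated correlation). Of them 0 passed over all genes, and 2 passed when adjusted over the list alone. Against the control mean the median log2 difference of the list was 1.45, 0.73 and 0.14 in E2 libraries 1, 2 and 3, whose weak-gene levels were 354, 156 and 44.8 counts per kb. Its member with the highest mean, MZT7_GM001710 (Sugar_tr), had a log2 change of -0.11 (SE 0.36).

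ABC transporters had 263 tested members and a median log2 change of 0.90, with 197 positive (camera adjusted p = 1.58e-04, and adjusted p = 0.814 with an estimated correlation). The list median was 1.31, 0.67 and 0.03 in E2 libraries 1, 2 and 3. Its member with the highest mean was MZT7_GM001361, which was lower with E2, against the direction of the list. Monooxygenases, dioxygenases and cytochromes P450 had 11 tested members and a median log2 change of 1.71, with 9 positive (camera adjusted p = 0.0425, and adjusted p = 0.814 with an estimated correlation). Their median was 2.29, 1.23 and 0.06 in E2 libraries 1, 2 and 3. The list's median control level was 22.1 FPKM, and its member with the highest mean, MZT7_GM001708 (FAD_binding_3), had a log2 change of -0.19 (SE 0.34). Translation factors and aminoacyl-tRNA synthetases had 17 tested members and a median log2 change of -0.42, with 4 positive (camera adjusted p = 0.0209, and adjusted p = 0.814 with an estimated correlation). Their median was -0.97, -0.52 and 0.00 in E2 libraries 1, 2 and 3, and MZT7_GM003470 (GTP_EFTU) had the highest mean, with a log2 change of -0.97 (SE 0.69). In all 4 lists 0 members passed the edgeR test over all genes, and adjusted over the list alone 0 passed in the ABC transporter, monooxygenase and translation lists. The median control level was 36.1 FPKM in the major facilitator list, 28.2 in the ABC transporter list and 252 in the translation list. Over all tested features it was 112. The higher lists thus lay below that level and the lower list above it, as in the shift of weak and strong genes in E2 libraries 1 and 2.

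The other 13 lists did not pass camera. Short-chain dehydrogenases, the list nearest to steroid conversion, had 13 tested members with 8 positive and a median log2 change of 0.14 (camera adjusted p = 0.806). Besides MZT7_GM000095, the member with the highest mean was MZT7_GM003361, with a log2 change of -0.69 (SE 0.36). Fatty acid beta-oxidation had 28 members with a median of 0.38 (camera adjusted p = 0.228), fatty acid biosynthesis 6 with -0.52 (0.228) and the tricarboxylic acid cycle 7 with -0.40 (0.392). The beta-oxidation member with the highest mean, MZT7_GM000920 (Thiolase_N), had a log2 change of -0.66 (SE 0.62), MZT7_GM001059 (ketoacyl-synt) one of -0.72 (SE 0.33) and MZT7_GM000926 (Aconitase) one of -0.83 (SE 0.53). TetR and MarR regulators had 51 members with 39 positive and a median of 0.30 (camera adjusted p = 0.106), and 2 passed when adjusted over the list alone. Chaperones and Clp proteases had 7 members and a median of 0.00 (camera adjusted p = 0.893), and MZT7_GM003272 (Clp_N) had a log2 change of -0.50 (SE 0.75). Medians of the remaining lists were -0.04 for iron uptake and storage, 0.19 for oxidative stress defence, 0.01 for DNA repair, 0.06 for sigma factors, 0.33 for two-component systems, -0.24 for amino acid synthesis and 0.52 for transposases.

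The most abundant features did not pass the edgeR test either. Novel00026 had the highest mean, with a log2 change of -0.87 (SE 1.15). Novel00034, MZT7_GM001386, MZT7_GM002763 and MZT7_GM001083 (Ferritin, an iron storage protein domain) had log2 changes of -0.82, -1.18, -1.06 and -0.73. No run of at least 4 neighbouring called genes occurred with 1 called gene. With genes at an unadjusted p under 0.05 there were 48 runs, against a median of 4 and a highest of 11 in 1000 shuffles (permutation p = 0.000999, the smallest that 1000 shuffles can give). Shuffling takes genes as independent, and neighbouring genes of bacteria are often transcribed together.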

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

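Limma-trend on log2(FPKM + 1) was the test fixed at the outset and became an alternative once counts were found. Alternatives with DESeq2, the covariate, subtraction, pairs of left-out libraries, features left out and unadjusted p were chosen after seeing the data. The counts of higher and lower features, 1 and 0 by edgeR, were 0 and 0 by limma-trend with a pseudocount of 0.1 or 1, without trend and with quantile normalisation, and 3 and 2 for libraries scaled to equal totals, which shifted the median log2 change of all features to 0.57. They were 3 and 32 by DESeq2 (3 and 29 at a log2 change of at least 1), 14 and 2 with the covariate, 0 and 0 without E2 replicates 1 and 2, where the 1 E2 library left is assumed to vary like the controls, and 43 and 24 (32 and 19) without control replicate 3 and E2 replicate 1. Leaving out 1 library gave 0 to 831 higher and 0 to 292 lower (0 to 809 and 0 to 198 at a log2 change of at least 1). The high values came without E2 replicate 3. They were 1 and 0 with a pseudocount of 10, no filter, a mean FPKM of at least 10, median-of-ratios factors, subtraction (where the call was MZT7_GM003584) and with coding genes only. The cause of these moves was not tested, apart from what is given under the other observations.

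The replicate block called 847 higher and 297 lower (747 and 75 at a log2 change of at least 1). The labels do not say that a number links a control with an E2 sample, so the numbers were not taken to pair the samples. Same-numbered libraries deviated together with correlations of 0.57, -0.07 and 0.69. For E2 libraries 1 and 3 the same-numbered control had the highest correlation. E2 library 2 had 0.02, -0.07 and 0.03 with controls 1, 2 and 3, so it cannot speak to pairing. Control 2 deviated most like E2 library 1, with a correlation of 0.39. Whether the numbers pair the samples stays open. In simulated libraries with an even background, the block called 1346 unchanged genes, but the RNA part of those libraries was not scaled as fitted to the data.

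Lists higher and lower, 3 and 1 by camera, were 1 and 0 with quantile normalisation and 0 and 0 with an estimated correlation. Lists higher were 2 under 12 alternatives, among them limma-trend, the covariate, equal totals and leaving out any control or E2 replicate 1. Lists lower were 0 with the covariate and without E2 replicates 1 and 2, and 0 to 1 over the left-out libraries, with 0 without control replicate 2. Runs were 48 at an unadjusted p under 0.05 and 9 with the covariate as well.

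Of 1221 values of named genes under alternatives, 1034 kept direction and side of the threshold, 143 newly passed it, 10 no longer passed and 34 turned direction. Those that turned belonged to genes with log2 changes by edgeR between -0.87 and 1.09, did not pass before or after, and the cause was not tested. With quantile normalisation they were 0.10 for MZT7_GM003361, 0.27 for MZT7_GM001708, 0.32 for MZT7_GM000920, 0.45 for MZT7_GM001710, 0.20 for MZT7_GM001083 and 0.15 for MZT7_GM003272. After subtraction they were 0.018, 0.30, 0.093, 0.49, 0.011 and 0.056 in the same order, and -0.064 for MZT7_GM002778. With the covariate MZT7_GM001708, MZT7_GM000920, MZT7_GM001710, MZT7_GM001083, MZT7_GM003272, Novel00026 and Novel00034 had 0.35, 0.22, 0.55, 0.26, 0.61, 0.20 and 0.27. Scaled to equal totals, MZT7_GM001708 had 0.23 and MZT7_GM001710 had 0.32. Without E2 replicates 1 and 2, MZT7_GM001708, MZT7_GM001710, MZT7_GM003272 and Novel00034 had 0.23, 0.36, 0.15 and 0.032. Without control replicate 3 and E2 replicate 1, MZT7_GM001708, MZT7_GM001710, MZT7_GM001083 and MZT7_GM003272 had 0.18, 0.36, 0.045 and 0.34. Over the left-out libraries MZT7_GM001708 ranged from -0.49 without E2 replicate 3 to 0.059 without E2 replicate 1, and MZT7_GM001710 from -0.45 to 0.13 likewise, with 0.087 without control replicate 3. MZT7_GM002921 ranged from -0.48 without E2 replicate 3 to 0.59 without E2 replicate 1.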

Other observations

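The tests below with the covariate, on subtraction, on the label of E2 library 3 and on the 8-gene stretch were chosen after results on the same question had been seen. With the weak-gene level as a covariate, an alternative chosen after seeing the data, edgeR called 14 features higher and 2 lower with E2. In the 8-gene stretch, MZT7_GM000630 (E1-E2_ATPase) had a log2 change of 4.19 (edgeR adjusted p = 0.00352), MZT7_GM000631 one of 3.78 (0.00161) and MZT7_GM000633 (Usp) one of 2.79 (0.00212), against 2.30, 2.27 and 1.95 without the covariate. MZT7_GM000627 in the same stretch went the other way, with 0.18 against 1.74. Outside it, MZT7_GM000969, a second cation pump domain gene (E1-E2_ATPase), had a log2 change of 2.22, MZT7_GM000121 (BPD_transp_2, a transporter permease domain) one of 2.26 and MZT7_GM000432 (GntR, a regulator family) one of 1.78, against 1.43, 1.22 and 0.79 without the covariate. MZT7_GM002778 and MZT7_GM002779, neighbours with no domain name, had 2.06 and 2.68, and MZT7_GM002921 had 1.24, against 1.09, 1.52 and 0.27 without it. In MZT7_GM000121, MZT7_GM000432, MZT7_GM002778, MZT7_GM002779 and MZT7_GM002921, E2 library 1 lay below control 3 in FPKM, so the groups overlapped. MZT7_GM002921 was at 170, 254 and 670 FPKM in E2 libraries 1, 2 and 3, and at 242, 258 and 431 in controls 1, 2 and 3. MZT7_GM002633 (MFS_1) had -2.15, against -0.68 (SE 0.51, edgeR adjusted p = 0.366) without the covariate, where its groups overlapped, and MZT7_GM003281 had -1.61, against -1.56. The other features called higher with the covariate were MZT7_GM000628, MZT7_GM000626, MZT7_GM003584, MZT7_GM003583 and MZT7_GM000096. Their log2 changes were 2.31, 2.13, 2.26, 1.88 and 1.49 (edgeR adjusted p from 0.00357 to 0.0197). Without the covariate they were 2.43, 2.35, 1.98, 1.40 and 1.25. In each of them every E2 library lay above every control. Of the genes named in this paragraph, MZT7_GM000628 alone passed the edgeR test without the covariate. With 6 libraries and 1 added term this fit leaves few degrees of freedom, and the covariate itself differs between the groups.

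The single call was weighed against chance by splitting the 6 libraries. Of the 10 splits into 3 and 3, 1 gave as many called genes, which was the real split with 1, and the highest of the others was 0. With 10 splits a share under 0.05 cannot be reached.

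E2 libraries 1 and 2 had weakly expressed genes higher and strongly expressed genes lower than the controls. Counts spread evenly along the genome, as from residual genomic DNA, could give this, and would make counts per kb more alike between weak genes. The coefficient of variation over 323 weak features was 0.400 in E2 library 1 and 0.351 in E2 library 2, against 0.441, 0.373 and 0.765 in the controls, so E2 library 1 lay above control 2, by 0.0269 (bootstrap SE 0.0167), and E2 library 2 differed from it by -0.0224 (SE 0.0146). By the bound set beforehand the value of E2 library 1 counts against an even background. That bound let 1 of the 2 libraries decide, while E2 library 2 lay on the other side by more than its SE. These genes are also near the floor. The line estimate gave controls 1 and 2 intercepts of 107 and 60.7 counts per kb, above their weak-gene levels of 57.9 and 49.2. Those controls may thus hold background too and are no background-free reference. The comparison cannot decide, and the explanation stays open. A response of the cells to E2 was not tested and stays open, and E2 library 3, with a median of 0.10 for weakly expressed genes, lay within the controls, at -0.75 to 0.37.

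Without E2 replicate 3 the number of edgeR calls went from 1 to 1123, of which 100% of the rises lay below and 99.3% of the falls above the median control level of 112 FPKM. On the 2888 features with counts above the estimated even background, the same test without that library called 2, and voom with limma called 2 before and 1 after subtraction, too few for subtraction to be tested. The estimate lay above the weak-gene level in E2 libraries 1 and 2, so this filter may leave out expressed genes. In simulated libraries with an even background, leaving out E2 replicate 3 called 1 unchanged gene. The RNA part of those libraries was not scaled as fitted to the data, so that simulation cannot speak to the rise. A mislabelled control as E2 library 3 could also matter. After subtraction, at 50 genes picked without it and without 1 control, it lay further to the E2 side than the left-out control at 32, 36 and 34 genes (exact binomial p = 0.0649, 0.00260 and 0.0153, with 25 by chance). This did not reach the bound set for every control. The exact test takes the 50 genes as independent, while genes of 1 library can move together, so its p-values cannot settle the label. Other values go with the label, since E2 library 3 was at 120 FPKM for MZT7_GM000628 against 20.1 to 28.8 in the controls, and at 435 for MZT7_GM003584 against 75.3 to 112. Both genes were also called by edgeR without that library (adjusted p = 0.0312 each), among 1123 calls. They were named from fits that included E2 library 3 and are not the set, so they do not decide the label. An earlier form of the test on 50 picked genes found E2 library 3 beyond all 3 controls at 38 of 50 genes, but its chance level of 25% did not hold for genes picked on the same controls.

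The stretch from MZT7_GM000626 to MZT7_GM000633 was higher with E2 by a mean log2 difference of 2.03 (SE 0.58), with the lowest E2 library 0.52 above the highest control. An even background could add to this difference. After subtraction it was 2.26 (SE 1.57), and E2 library 1 then lay among the controls, at a mean log2 level of 2.98 against 2.42 to 4.88, while E2 libraries 2 and 3 were at 6.97 and 7.31. The difference did not shrink but its spread grew, in both groups. E2 library 1 fell from 5.83 to 2.98, and control 1 from 4.64 to 2.42. In E2 library 1 the intercept of the estimate was 640 counts per kb, above the weak-gene level of 354. Subtraction may take off more than an even background there, so the test did not decide. A response of these genes to E2 stays open.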
